A study of Homo sapiens and Mus musculus with 25 samples.

How the data were processed

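Histone modifications were mapped in K562, an established human cell line derived from a chronic myeloid leukaemia and widely used as a model of erythroid progenitors. The assay was internally calibrated ChIP-seq, in which semi-synthetic nucleosomes that carry a known modification and a DNA barcode are spiked into the chromatin before the immunoprecipitation. Recovery of these standards puts the signal at each locus on a scale of modification density, per the labels. The peak lists of 17 antibodies raised against methylated lysine 4 of histone H3 were compared, of which 5 were raised against H3K4me1, 4 against H3K4me2 and 8 against H3K4me3. One list each for H3K9me3 and H3K27me3 was used beside them. A further 3 corrected lists, 1 per degree of H3K4 methylation, were computed by the authors from the Abcam ab8895, ab7766, ab12209 and ab8580 libraries to remove off-target capture, per the deposited notes. These 22 lists come from a series of 25 samples, and the other 6 samples, which are 2 K562 inputs and 4 mouse embryonic stem cell samples, were not analysed here.

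The submitters' processing notes name Bowtie2, SAMtools, bedtools, MACS2 and the build GRCh38 (hg38), and their versions are not given in the sources used here. Each antibody has its own list, so replicate antibodies were not pooled by the authors. The calling settings, and the rule by which a peak was kept as high confidence, are not given in the sources used here. In 17 lists the authors deposited a signal value for each peak. No header names it, and it is read here as an apparent modification density on the calibrated scale. A density in percent cannot exceed 100, but 1 value in the Abclonal A2357 list (102.7) and 4 in the corrected H3K4me3 list (up to 107.5) do, so this reading is uncertain. It is called the authors' value and was used to describe and filter peaks within a list. Its median was also compared between targets, as fixed before the data were examined, although such values are best compared within a list. The other 5 lists (Abcam ab8580, Diagenode C15410003, EpiGentek A-4033-050, H3K9me3 and H3K27me3) have positions only. Read depth is unknown for peak lists, so no counting interval or detection limit was computed. A window without a listed peak therefore does not show an unmodified promoter.

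Antibodies were grouped by the target in the labels, and each antibody gave 1 value. The labels name no separate cultures, so p-values measure the spread between antibodies on K562 chromatin and not between biological replicates. Of the 17 libraries, 15 were run beside the AR16 input and 2 H3K4me3 libraries beside the AR17 input. Amplification took 12 cycles for 4 libraries (EMD Millipore 05-1338, Abcam ab12209, Abclonal A2357 and Thermo Fisher PA5-40086) and 8 cycles for the other 13.

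Peaks on chromosomes 1 to 22 and X were kept, and 0 peaks lay outside the reference sequences. Covered length was counted after merging overlapping peaks. Promoters were windows of 1 kb either side of the transcription start site (TSS) of the canonical transcript of 19962 protein-coding genes in GENCODE release 44. The canonical TSS was chosen over the 5′ end of the gene after a first look at the annotation, because for 3311 genes the 2 lie over 1 kb apart. A promoter held a peak when at least 1 base overlapped. Occupancy at the TSS was the percent of TSS bases under a peak minus the mean percent of bases 3 kb up- and downstream under a peak, in percentage points. The Jaccard index of 2 lists was the bases shared divided by the bases in either list.

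Means of 9 measures were compared between each pair of targets by exact two-sided permutation tests over all regroupings of the antibodies, with Benjamini-Hochberg adjustment over the 27 tests and a threshold of 0.05 on the adjusted p. The smallest p these tests can give is 0.0159 for 5 against 4 antibodies, 0.00155 for 5 against 8 and 0.00404 for 4 against 8. Grouping of lists by target was tested by 100000 shuffles of the target over the antibodies. For 12 gene lists (erythroid, housekeeping, cell cycle, H3K4 methylation writers and erasers, myeloid, lymphoid, neural, liver, HOX, developmental transcription factors, chromosome 19 zinc finger genes and olfactory receptors), the share of promoters with a peak minus that of all genes was compared by the same exact test, adjusted over 36 tests. Single lists were compared with all other genes by Fisher's exact test, adjusted over 60 tests, which runs across genes and not replicates. The gene lists, measures, tests, alternatives and the rule for named genes were fixed before the data were examined. Distal regions were also named then, but their test, the promoter classes and 3 alternatives (without chromosomes 13, 14 and X, without peaks over 1 Mb, and with the TSS at the 5′ end of the gene) were chosen after seeing the data.

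The rule for named genes took, from each gene list, the 2 genes whose promoters held a peak in the most and the 2 in the fewest of the 17 H3K4 lists, ties going to the longer corrected H3K4me3 peak and then the alphabet. It also took the 10 genes with the widest corrected H3K4me3 peak at the promoter, the 10 with the widest corrected H3K4me1 peak and no corrected H3K4me3 peak, and the 10 with the widest H3K27me3 peak. Some of the genes this rule took are not reported here. The distal regions were 6 to 22 kb upstream of HBE1, 1.8 to 2 Mb downstream of MYC and 3 to 5 kb upstream of GATA1.

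The alternatives were peaks at or above each list's median value (or width, without values), merging of peaks within 1 kb, dropping peaks under 200 bases, all sequences, overlap by at least 0.5 of the peak or window, windows of 2.5 and 0.5 kb, flanks at 2 and 5 kb, a log2 scale, width-weighted values, the overlap coefficient, antibodies of the AR16 input alone, libraries of 8 cycles alone and leaving out each antibody. Computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9. The exact test was tested on simulated data of 5 against 8 antibodies: of 400 simulated comparisons it called 5.5% with no difference and 99.75% with a difference of 3 SD. The simulated groups were normal with equal spread and were called at an unadjusted p under 0.05. These rates therefore do not describe groups of unequal spread or the adjusted threshold.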

Results

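The data map methylation of lysine 4 of histone H3 in K562 leukaemia cells with 17 antibodies, 5 against the mono-, 4 against the di- and 8 against the trimethylated form, each giving 1 list of peaks on the GRCh38 genome. H3K4me1 is classically found at enhancers and beside promoters, and H3K4me3 at active and poised promoters. The series compares antibodies of 1 stated target, so the spread is given between antibodies. Lists ranged from 13311 peaks (EpiGentek A-4033-050, H3K4me3) to 721215 peaks (Abcam ab8580, H3K4me3) on chromosomes 1 to 22 and X. Read depth behind the lists is unknown.

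The first comparison asked how much of the genome and how many promoters each mark covered. H3K4me1 peaks covered 1103 ± 317 Mb (SD, n = 5 antibodies), H3K4me2 peaks 784 ± 602 Mb (n = 4) and H3K4me3 peaks 138 ± 260 Mb (n = 8). The median H3K4me3 list covered 31.6 Mb, and the mean without Abcam ab8580 was 47.8 Mb, while Abcam ab8580 covered 769 Mb, more than the H3K4me1 list of Thermo Fisher 710795 at 723 Mb. Promoters with a peak made up 78.0% ± 5.16 of 19962 protein-coding genes for H3K4me1 (SD, n = 5), 76.0% ± 7.12 for H3K4me2 (n = 4) and 54.9% ± 13.8 for H3K4me3 (n = 8). Promoters with a peak in all 17 lists numbered 5573, and 1539 promoters had none. The difference between H3K4me1 and H3K4me3 was larger than the spread between antibodies for covered length (965 Mb, exact permutation p = 0.00311, adjusted p = 0.0210) and for promoters (23.1 percentage points, exact permutation p = 0.00311, adjusted p = 0.0210). H3K4me2 did not pass the adjusted threshold against H3K4me3 in covered length (646 Mb, exact permutation p = 0.0444, adjusted p = 0.109) or promoters (21.0 points, adjusted p = 0.0682 from the exact test). Against H3K4me1 it differed by 319 Mb (adjusted p = 0.451, exact test) and 2.07 points (adjusted p = 0.708, exact test).

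**Figure D1:**
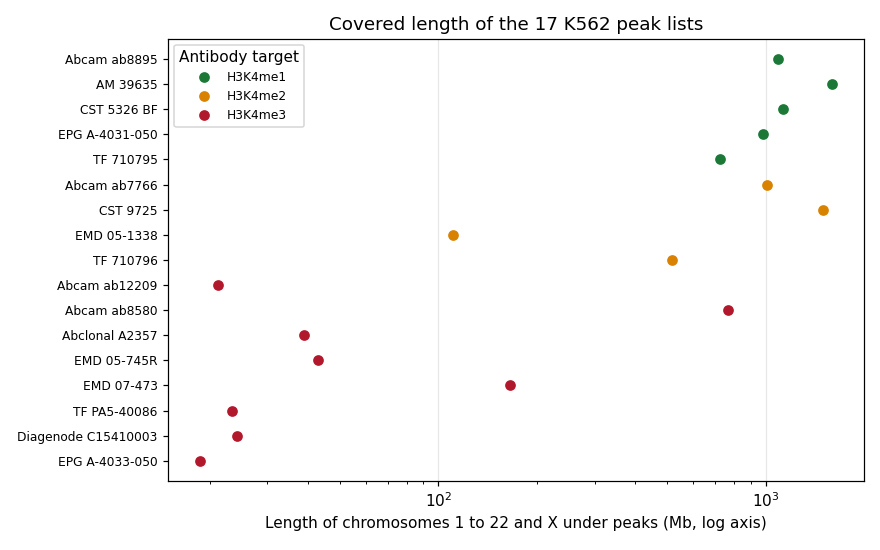
Length of chromosomes 1 to 22 and X under peaks (Mb, log axis) for each of the 17 antibodies, 1 point per list, coloured by target. The H3K4me1 lists lie between 723 and 1593 Mb, and the H3K4me3 lists between 18.7 Mb and the 769 Mb of Abcam ab8580.

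Peaks at promoters were 37.3% ± 23.8 of all H3K4me3 peaks (SD, n = 8), 8.35% ± 9.30 of H3K4me1 peaks (n = 5) and 6.18% ± 5.80 of H3K4me2 peaks (n = 4). Abcam ab12209 had the highest promoter share, 66.8% of 14172 peaks, and Abcam ab8580, of the same target, the lowest of all lists, 2.15%. Without Active Motif 39635 the H3K4me1 mean was 4.19%, below the mean of the 4 H3K4me2 lists. The peaks of Active Motif 39635 were wide, with a median of 25008.5 bases, so they reach a promoter more often. Without EMD Millipore 05-1338 the H3K4me2 mean was 3.28%. These differences did not pass the adjusted threshold for H3K4me1 against H3K4me3 (exact permutation p = 0.0249, adjusted p = 0.0746), for H3K4me2 against H3K4me3 (exact permutation p = 0.0364, adjusted p = 0.0982) or for H3K4me1 against H3K4me2 (exact permutation p = 0.571, adjusted p = 0.701). Peak numbers averaged 397306 ± 219872 for H3K4me1 (SD, n = 5), 365116 ± 171627 for H3K4me2 (n = 4) and 134339 ± 248774 for H3K4me3 (n = 8). With all lists no pair of targets differed in number beyond the spread, with adjusted p = 0.857 for H3K4me1 against H3K4me2, 0.165 for H3K4me1 against H3K4me3 and 0.218 for H3K4me2 against H3K4me3 in the exact tests. Without Abcam ab8580 the H3K4me3 mean was 50500 peaks, and H3K4me1 (exact test, adjusted p = 0.0227) and H3K4me2 (exact test, adjusted p = 0.0273) both exceeded it. The authors' median value per peak was 12.2 ± 7.29 for H3K4me1 (SD, n = 5), 9.10 ± 0.560 for H3K4me2 (n = 4) and 18.0 ± 8.46 for the H3K4me3 lists that hold values (n = 5), with no pair past the threshold (exact tests, adjusted p = 0.804, 0.378 and 0.165). These values are best compared within a list. Weighted by peak width, the value was lower than for H3K4me3 in H3K4me1 lists (-11.8, exact test, adjusted p = 0.0476) and in H3K4me2 lists (-14.1, exact test, adjusted p = 0.0476).

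Occupancy at the TSS was then compared with that 3 kb away. H3K4me1 was lower at the TSS than 3 kb away, by -20.8 ± 8.76 percentage points (SD, n = 5), and was so in all 5 lists. H3K4me2 was higher at the TSS by 11.9 ± 12.3 points (n = 4) and H3K4me3 by 38.3 ± 11.8 points (n = 8), in every list of each. In the H3K4me2 list of Cell Signaling Technologies 9725 the difference was only 0.271 points. Without EMD Millipore 05-1338 the H3K4me2 mean was 6.37 points. H3K4me1 differed from H3K4me3 by -59.1 points (exact permutation p = 0.00155, the smallest possible, adjusted p = 0.0210). H3K4me1 against H3K4me2 (-32.7 points, exact permutation p = 0.0159, adjusted p = 0.0612) and H3K4me2 against H3K4me3 (-26.4 points, exact permutation p = 0.0121, adjusted p = 0.0545) did not pass after adjustment.

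**Figure D2:**
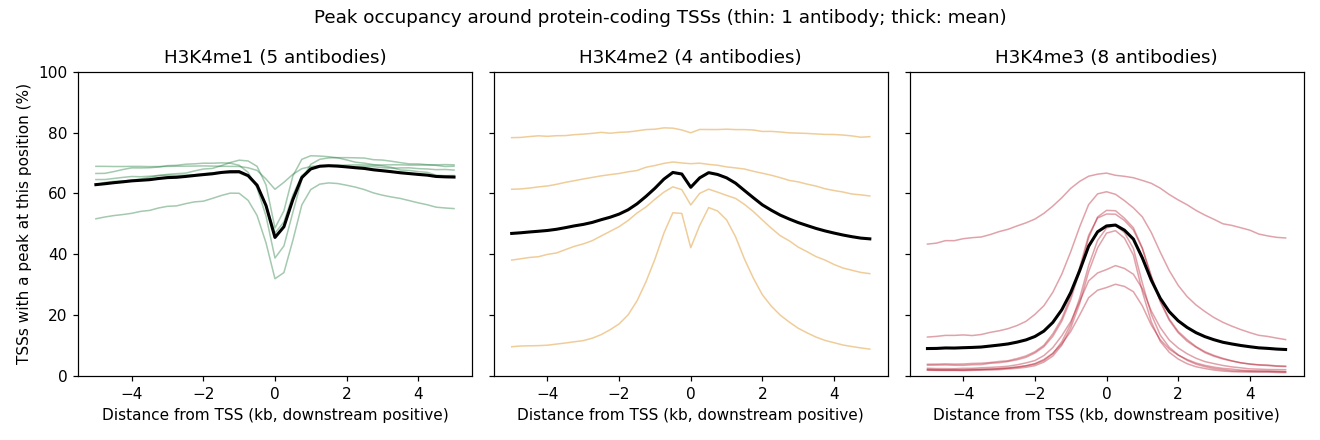
Percent of 19962 protein-coding TSSs with a peak at each distance (kb, downstream positive) for H3K4me1, H3K4me2 and H3K4me3, thin lines for single antibodies and thick lines for the mean. The H3K4me1 lists dip at the TSS, by -20.8 points on average relative to 3 kb away, and the H3K4me3 lists peak there, by 38.3 points.

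Of these 27 comparisons of targets, 4 passed the threshold, all between H3K4me1 and H3K4me3, and 11 had an unadjusted p under 0.05. One of the 4, the share of covered length in the corrected H3K4me3 list, is bounded by list length and so repeats the call for covered length. All 4 calls ended with the AR16 antibodies alone (adjusted p = 0.0584, exact tests) and with the libraries of 8 cycles alone (adjusted p = 0.107, exact tests). They also ended without Abcam ab8895, Cell Signaling Technologies 5326 BF or EpiGentek A-4031-050 (exact tests, adjusted p = 0.0545 each), the direction staying the same. The call for covered length also ended without Active Motif 39635 (843 Mb, exact test, adjusted p = 0.0545). That for promoters ended without Thermo Fisher 710795 (23.2 points, exact test, adjusted p = 0.0545), with peaks at or above each list's median value, with overlap by 0.5 of the window or with a window of 2.5 or 0.5 kb (exact tests, adjusted p = 0.0524 to 0.0801). Without Abcam ab8580, a further 9 comparisons passed. They were H3K4me1 against H3K4me3 in number and promoter share of peaks (exact tests, adjusted p = 0.0227 each), H3K4me1 against H3K4me2 in TSS occupancy (exact test, adjusted p = 0.0330) and 6 of H3K4me2 against H3K4me3 (exact tests, adjusted p = 0.0273 each). These 6 were in number of peaks, covered length (736 Mb), promoter share of peaks, promoters, TSS occupancy and share in the corrected H3K4me3 list.

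Peaks of antibodies against the same target overlapped more than peaks of antibodies against different targets. The mean Jaccard index was 0.386 within targets and 0.175 between targets, a difference of 0.211 (permutation p = 0.00131, 17 antibodies). H3K4me1 lists shared 0.558 on average over 10 pairs, H3K4me3 lists 0.346 over 28 pairs and H3K4me2 lists 0.286 over 6 pairs, while H3K4me1 and H3K4me2 lists shared 0.418 over 20 pairs. The H3K4me2 mean was lowered by EMD Millipore 05-1338, whose pairs with the other H3K4me2 lists shared 0.0709 to 0.190. Pairs among those other lists shared 0.328 to 0.589. The closest pair was Abcam ab12209 and Thermo Fisher PA5-40086, both H3K4me3, at 0.865. The nearest list had the same target for 10 of the 17 antibodies. For all 4 H3K4me2 lists the nearest had another target: EMD Millipore 05-1338 was nearest to the H3K4me3 list of EMD Millipore 07-473 (0.482), and Cell Signaling Technologies 9725 to the H3K4me1 list of Active Motif 39635 (0.691). Abcam ab8580, sold against H3K4me3, was nearest to the H3K4me1 list of Abcam ab8895 (0.458). The index depends on list length, and with the overlap coefficient in its place the difference was 0.0633 (permutation p = 0.00099).

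**Figure D3:**
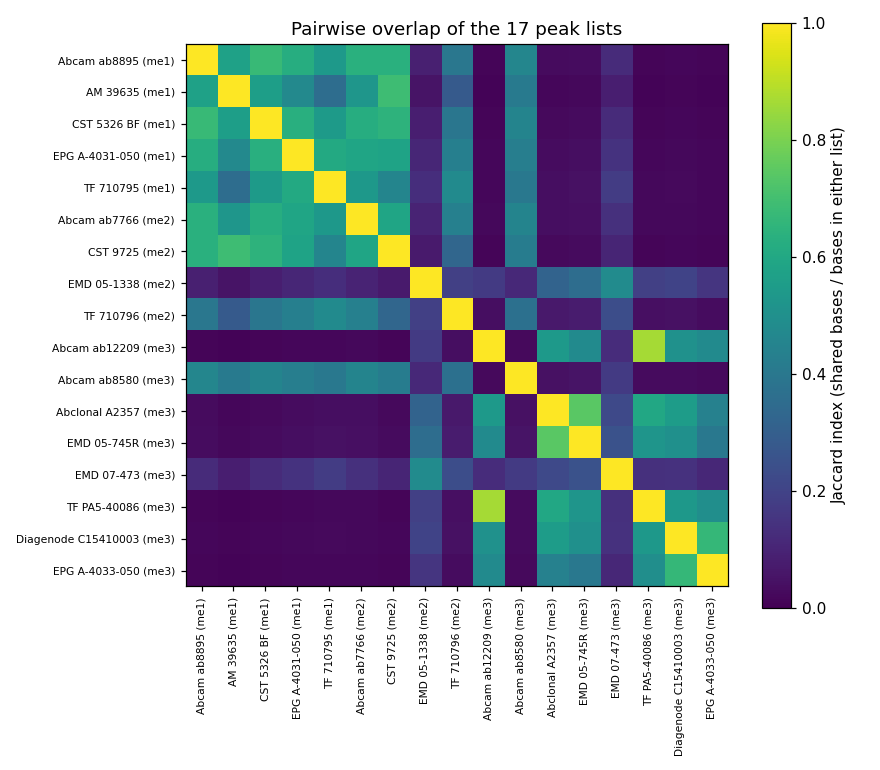
Jaccard index (shared bases over bases in either list, colour scale from 0 to 1) for each pair of the 17 peak lists, ordered by target. Most H3K4me1 and H3K4me2 lists form 1 block, while 7 of the 8 H3K4me3 lists lie outside it and Abcam ab8580 shares more with it, up to 0.458.

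Gene lists were used to ask at which kinds of promoter each mark lay. Promoters of cell cycle genes had a peak in 87.5% ± 14.1 of cases in the H3K4me3 lists (SD, n = 8), and those of H3K4 methylation writers and erasers in 84.2% ± 16.6. The share was 79.8% ± 10.8 for chromosome 19 zinc finger genes, which encode mostly KRAB repressors, 77.7% ± 12.8 for housekeeping genes and 75.5% ± 9.18 for erythroid genes. Of the groups of other lineages, myeloid genes had 34.2% ± 25.8, lymphoid genes 22.2% ± 27.5, neural genes 15.8% ± 13.5 and liver genes 13.2% ± 27.8. Olfactory receptor genes, which are expressed in the nose, had 9.72% ± 20.3. Abcam ab8580 raised these means, with peaks at 81.8% of lymphoid, 77.8% of liver and 58.5% of olfactory receptor genes. Without it the means were 13.6%, 3.97% and 2.75%. HOX genes had 36.9% ± 28.6 and developmental transcription factors 28.9% ± 20.6. H3K4me1 lists, at 78.0% of all promoters, held peaks at 85.3% ± 2.98 of myeloid (SD, n = 5), 87.3% ± 4.98 of lymphoid, 81.1% ± 4.97 of liver and 91.3% ± 6.69 of HOX genes. Their share was 49.5% ± 4.71 for neural genes (SD, n = 5), 56.7% ± 8.14 for developmental transcription factors and 57.0% ± 9.24 for olfactory receptors.

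Relative to all promoters, H3K4me1 exceeded H3K4me3 at liver genes by 44.8 points (exact permutation p = 0.00622, adjusted p = 0.0448), at lymphoid genes by 42.0 points (exact permutation p = 0.00311, adjusted p = 0.0373) and at myeloid genes by 28.1 points (exact permutation p = 0.00466, adjusted p = 0.0420). On the same relative measure it was lower than H3K4me3 at H3K4 methylation writers and erasers (-22.1 points, exact permutation p = 0.00155, adjusted p = 0.0280) and at chromosome 19 zinc finger genes (-17.6 points, exact permutation p = 0.00155, adjusted p = 0.0280). H3K4me2 was lower than H3K4me3 on this measure at the zinc finger genes too (-12.5 points, exact permutation p = 0.00808, adjusted p = 0.0485). The plain shares ran the other way. They were 85.3% ± 4.40 for H3K4me1 and 84.2% for H3K4me3 at writers and erasers, and 85.3% ± 5.99 for H3K4me1, 88.4% ± 4.06 for H3K4me2 and 79.8% for H3K4me3 at the zinc finger genes. The negative differences arise because H3K4me1 and H3K4me2 lie at more of all promoters (78.0% and 76.0%) than H3K4me3 (54.9%). These 6 of 36 tests passed, and 14 had an unadjusted p under 0.05. The erythroid (-11.7 points), HOX (31.3), neural (10.6) and olfactory receptor genes (24.1) did not pass between H3K4me1 and H3K4me3, each with an exact adjusted p of 0.0503. Nor did the housekeeping (-14.7 points, 0.0509), cell cycle (-15.6 points, 0.0793) and developmental genes (4.68 points, 0.444) by the same exact tests. No call was left with the AR16 antibodies, with 8-cycle libraries, with a 2.5 kb window, or without Abcam ab8895, Active Motif 39635, Cell Signaling Technologies 5326 BF or Thermo Fisher 710795 (0 calls each). There were 3 calls without EpiGentek A-4031-050 and 12 without Abcam ab8580. There were 2 without any 1 of Abcam ab12209, Abclonal A2357, EMD Millipore 05-745R, EMD Millipore 07-473, Thermo Fisher PA5-40086 or Diagenode C15410003.

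**Figure D4:**
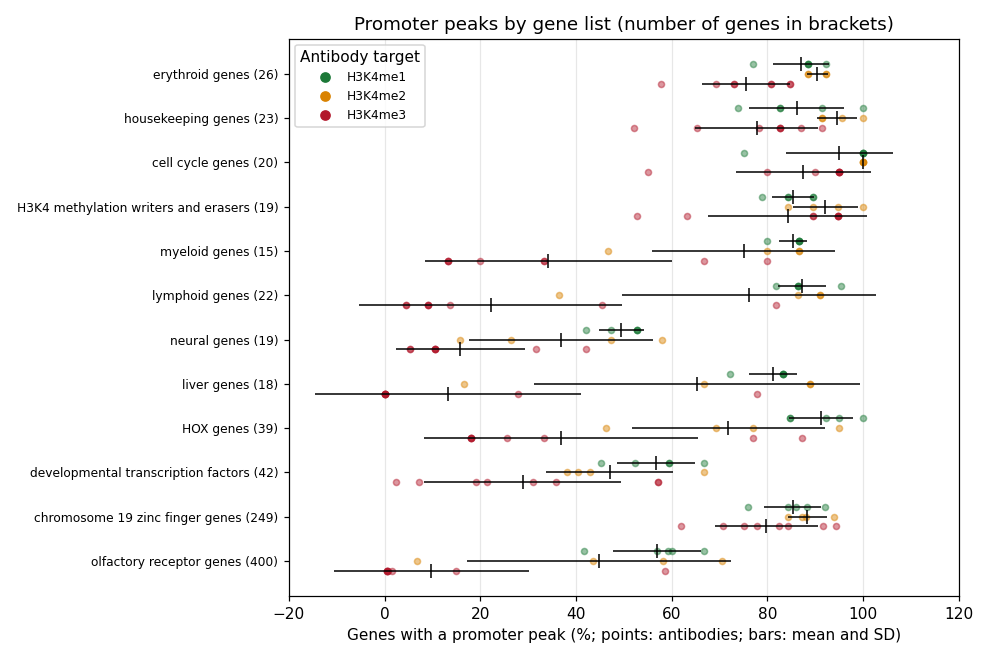
Percent of the genes of each list with a promoter peak, points for single antibodies coloured by target, with horizontal bars for SD around the mean. H3K4me3 points lie low for olfactory receptor genes, with a mean of 9.72%, except Abcam ab8580 at 58.5%, and high for cell cycle genes, with a mean of 87.5%.

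Single promoters showed the same range. Of 26 erythroid genes, 19 had a promoter peak in at least 5 of 8 H3K4me3 lists. TFRC, the transferrin receptor (chromosome 3, TSS 196082090), and TAL1, a transcription factor of blood development (chromosome 1, TSS 47232225), had one in all 17 H3K4 lists, with corrected H3K4me3 peaks of 5077 and 4238 bases. Only these 2 of the 26 erythroid promoters (7.69%) held a corrected H3K4me3 peak, against 18.1% of other genes. GYPB, for a red cell surface protein (chromosome 4, TSS 144019380), had a peak in 1 list. The count was 19 of 20 for cell cycle genes. CDC20, an activator of the anaphase-promoting complex (chromosome 1, TSS 43358981), and MCM7, a subunit of the replicative helicase (chromosome 7, TSS 100101397), were in all 17 lists. MKI67, the source of the Ki-67 proliferation antigen (chromosome 10, TSS 128126423), was in 13 lists. Of the writers and erasers 18 of 19 were positive. ASH2L, a core subunit of the H3K4 methyltransferase complexes (chromosome 8, TSS 38105529), and PAXIP1, a partner of KMT2C and KMT2D (chromosome 7, TSS 155003124), were in all 17.

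Of 23 housekeeping genes 19 were positive, with the TATA-binding protein gene TBP (chromosome 6, TSS 170554369) and the proteasome gene PSMB2 (chromosome 1, TSS 35641526) in all 17 lists. GAPDH, the glycolytic enzyme gene (chromosome 12, TSS 6534517), had peaks in 8 lists and in 0 of the 8 for H3K4me3. HPRT1, for purine salvage (chromosome X, TSS 134460165), had them in 5 lists and likewise in 0 for H3K4me3. The helicase subunit gene MCM5 (chromosome 22, TSS 35400140) and the H3K4 demethylase gene KDM5C (chromosome X, TSS 53225207) were also in 0 H3K4me3 lists, and CXXC1, which binds unmethylated CpG (chromosome 18, TSS 50287692), in 5. A missing peak at these genes does not show a missing mark. Of 10896 CpG-rich promoters flanked by peaks of the H3K4me2 list of EMD Millipore 05-1338, 333 had no peak in any H3K4me3 list. These were 11.1% of those on chromosomes 13, 14 and X, which have few peaks in most H3K4 lists, and 2.41% of the others.

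Among genes of other lineages, 3 of 15 myeloid, 2 of 22 lymphoid, 2 of 19 neural and 0 of 18 liver genes were positive by the same count. CD33, a myeloid surface receptor (chromosome 19, TSS 51225080), was in all 17 lists, and SPI1, the myeloid transcription factor PU.1 (chromosome 11, TSS 47378547), in 16. The Fc receptor gene FCGR3A (chromosome 1, TSS 161549818) was in 0 and CTSG, for the neutrophil protease cathepsin G (chromosome 14, TSS 24576250), in 1. CD3D, of the T cell receptor complex (chromosome 11, TSS 118342705), was in 16 lists and EBF1, a B cell factor (chromosome 5, TSS 159099916), in 14. The B cell factor PAX5 (chromosome 9, TSS 37034268) was in 1 and CD5, a T cell surface protein (chromosome 11, TSS 61102489), in 3. Of neural genes SLC17A7, a vesicular glutamate transporter (chromosome 19, TSS 49441527), was in 16 lists, 8 of them for H3K4me3, and SYP, for synaptophysin (chromosome X, TSS 49200193), in 12. GRIN2B, a glutamate receptor gene (chromosome 12, TSS 13981602), and DCX, the doublecortin gene (chromosome X, TSS 111412192), were in 0 lists. So were the liver genes SERPINA1, for antitrypsin (chromosome 14, TSS 94388602), and F9, for coagulation factor IX (chromosome X, TSS 139530739). CTSG, DCX, SERPINA1 and F9 lie on chromosomes 14 and X, which have few peaks in most H3K4 lists. Their low counts therefore do not show a missing mark. The apolipoprotein gene APOC3 (chromosome 11, TSS 116829907) and the fibrinogen gene FGG (chromosome 4, TSS 154612656) were each in 11 lists, 2 of them for H3K4me3.

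Of 39 HOX genes, which pattern the body axis, 8 were positive. HOXB2 (chromosome 17, TSS 48545109) and HOXB4 (TSS 48578350) were in all 17 lists, and HOXA4 (chromosome 7, TSS 27130757) in 4. Of 42 developmental transcription factors 9 were positive, including TBX1 (chromosome 22, TSS 19760778), in all 17 lists, and the kidney and gonad factor WT1 (chromosome 11, TSS 32435539), in 16. The endoderm factor FOXA2 (chromosome 20, TSS 22584572) and the organizer gene GSC (chromosome 14, TSS 94770113) were in 0. Of 249 chromosome 19 zinc finger genes 197 were positive, with the neighbours ZNF146 (TSS 36215106) and ZNF565 (TSS 36214665) in all 17 lists, ZNF729 (TSS 22286441) in 0 and ZNF676 (TSS 22196951) in 1. Of 400 olfactory receptor genes 2 were positive, OR1F1 (chromosome 16, TSS 3188204) and OR2AT4 (chromosome 11, TSS 75096876), both in all 17 lists. OR10AG1 (chromosome 11, TSS 55969945) and OR10G3 (chromosome 14, TSS 21580076) were in 0. GSC and OR10G3 lie on chromosome 14, which has few peaks in most H3K4 lists, so their counts do not show a missing mark.

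Promoters were then classed by H3K4me3 lists, a grouping chosen after seeing the data. At 10558 promoters with a peak in at least 5 of 8 lists, H3K4me1 occupancy at the TSS was lower than 3 kb away by -40.0 ± 17.2 points (SD, n = 5), and at 6193 promoters in at most 1 list by -2.77 ± 1.38 points. H3K4me2 was higher at the TSS by 16.3 ± 18.3 points in the positive class (SD, n = 4) and by 0.277 ± 2.58 points in the negative class. In the positive class 1 of the 4 lists, Cell Signaling Technologies 9725, was lower at the TSS (-1.23 points), and the mean without EMD Millipore 05-1338 was 7.97 points. In the negative class the mean without it was -0.910 points, and 1.14 without Abcam ab7766 or 0.546 without Thermo Fisher 710796. The change between classes differed between H3K4me1 and H3K4me2 by -53.3 points (exact permutation p = 0.0159, the smallest possible), a p not adjusted for the choice of this comparison after seeing the data. For H3K4me3 itself the classes are circular.

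Regulatory regions fixed by distance were compared by the percent covered. The lists differ in how much of the ungapped genome they cover, on average 37.8% for H3K4me1, 26.9% for H3K4me2 and 4.63% for H3K4me3, so these differences largely repeat that in covered length. Among the H3K4me3 lists Abcam ab8580 covered 25.5% and the others 0.642% to 5.68%. Relative to its genome coverage, the mean list was 2.81-fold for H3K4me1, 7.21-fold for H3K4me2 and 9.98-fold for H3K4me3 upstream of HBE1. These values were 2.52, 3.91 and 5.95 downstream of MYC and 2.46, 7.05 and 28.1 upstream of GATA1, which is the other order, though a list that covers 37.8% of the genome has little room above it. The medians were 2.69, 4.27 and 7.90 upstream of HBE1, 2.44, 3.65 and 6.06 downstream of MYC and 2.69, 4.27 and 31.1 upstream of GATA1. For H3K4me2 the highest of the 4 lists reached 18.4 upstream of HBE1 and 17.7 upstream of GATA1, which raises those means. The interval 6 to 22 kb upstream of HBE1 (chromosome 11, 5275945 to 5291945) holds the beta-globin locus control region. It was covered to 99.6% ± 0.906 by H3K4me1 peaks (SD, n = 5), 92.4% ± 15.1 by H3K4me2 peaks (n = 4) and 28.7% ± 36.7 by H3K4me3 peaks (n = 8). The interval 1.8 to 2 Mb downstream of the MYC oncogene (chromosome 8, 129536231 to 129736231) was covered to 90.7% ± 6.01, 73.6% ± 33.0 and 19.5% ± 27.6. Without Abcam ab8580 the H3K4me3 means were 18.8% upstream of HBE1 and 10.4% downstream of MYC. The 2001 bases beginning 3 kb upstream of GATA1, the erythroid master regulator (chromosome X, 48781590 to 48783590), were covered to 80% ± 44.7, 91.9% ± 16.3 and 45.8% ± 28.4, Active Motif 39635 having 0 peaks there. H3K4me1 exceeded H3K4me3 upstream of HBE1 by 70.9 points (exact permutation p = 0.00155, adjusted p = 0.0140 over 9 tests) and downstream of MYC by 71.2 points (exact permutation p = 0.00311, adjusted p = 0.0140). Upstream of GATA1 the 34.2 points did not pass (exact test, adjusted p = 0.189), though without Active Motif 39635 they were 54.2 (exact test, adjusted p = 0.0364). H3K4me2 exceeded H3K4me3 in the 3 regions by 63.7, 54.1 and 46.0 points (exact tests, adjusted p = 0.0436 each), while H3K4me1 and H3K4me2 did not differ beyond the spread (exact tests, adjusted p = 1, 0.490 and 1). With the AR16 antibodies alone each of these H3K4me2 calls ended (exact tests, adjusted p = 0.103), and likewise with peaks within 1 kb merged (0.0606 to 0.0655). Each also ended without any 1 of Abcam ab7766, Cell Signaling Technologies 9725 and Thermo Fisher 710796 (0.109 or 0.131) or of the H3K4me3 lists other than Abcam ab8580 and EMD Millipore 07-473 (0.0655). Without EMD Millipore 05-1338 the MYC (0.0545) and GATA1 (0.0873) calls ended and without EMD Millipore 07-473 that of GATA1 (0.0545). With 8-cycle libraries alone all 3 H3K4me2 calls ended (exact tests, adjusted p = 0.107, 0.161 and 0.257), and the H3K4me1 calls at HBE1 and MYC ended too (exact tests, adjusted p = 0.0714).

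The corrected lists of the authors were described next, each without a replicate. Corrected H3K4me1 peaks covered 1014 Mb and 71.4% of promoters, corrected H3K4me2 peaks 320.0 Mb and 55.1%, and corrected H3K4me3 peaks 20.2 Mb and 18.1%. Corrected H3K4me1 and H3K4me2 without corrected H3K4me3 marked 7055 promoters, all 3 marks 3265, H3K4me1 alone 3680 and none 4983. The corrected H3K4me3 list marked only 3610 promoters, while 10558 had a peak in at least 5 of 8 H3K4me3 lists. A promoter without a corrected H3K4me3 peak is therefore not shown to lack H3K4me3. The widest corrected H3K4me3 peaks at promoters were 8459 bases at BRD2, a BET family bromodomain gene (chromosome 6, TSS 32968594), and 7816 bases over the divergent pair of GART, a purine synthesis enzyme gene (chromosome 21, TSS 33542117), and SON, a splicing factor gene (TSS 33543038). Peaks of 7623 bases lay at the homeobox gene TGIF1 (chromosome 18, TSS 3450172) and of 7334 bases at CPED1 (chromosome 7, TSS 120988711). A peak of 6918 bases covered the histone genes H2AC7, H2BC7 and H3C4 (chromosome 6, TSS 26199293, 26199516 and 26197286) and a gene without a symbol that shares the TSS of H2AC7, and one of 6875 bases KMT2E (chromosome 7, TSS 105014205). The widest corrected H3K4me1 peaks at promoters without corrected H3K4me3 were 245298 bases at MED13L, of the Mediator kinase module (chromosome 12, TSS 116277693), and 206902 bases at TEAD1, the DNA-binding partner of YAP (chromosome 11, TSS 12674421). They were followed by 194570 bases at SSBP3 (chromosome 1, TSS 54406394) and 185355 bases at ABL1, the kinase gene fused to BCR in K562 (chromosome 9, TSS 130835254), under the same peak as a gene without a symbol (TSS 130713626). NR6A1, ASH1L, DNAJC8, PTAFR and SPDEF had 181493 to 155706 bases. Most of these genes had promoter peaks in the single H3K4me3 lists. MED13L and DNAJC8 had them in all 8, SSBP3 in 7, and TEAD1, NR6A1 and ASH1L in 6. ABL1 had them in 3, and PTAFR and SPDEF in 2.

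By Fisher's exact test across genes, 7 of 60 list comparisons passed and 12 had an unadjusted p under 0.05. Corrected H3K4me1 was at 47.6% of developmental transcription factors against 71.4% of other genes (Fisher's exact test, adjusted p = 0.0140) and at 51.0% of olfactory receptors against 71.8% (adjusted p = 1.06e-16). The former call ended with a window of 2.5 kb (57.1% against 75.7%, exact test, adjusted p = 0.0885) and without chromosomes 13, 14 and X (60.6% against 75.8%, exact test, adjusted p = 0.226). Corrected H3K4me2 was at 15.8% of neural genes (exact test, adjusted p = 0.00709), 23.8% of developmental transcription factors (adjusted p = 0.000924), 24.8% of olfactory receptors (adjusted p = 1.04e-33) and, in the other direction, at 66.7% of chromosome 19 zinc finger genes against 54.9% of others (adjusted p = 0.00233). Of these, the call for developmental transcription factors ended with the 2.5 kb window (exact test, adjusted p = 0.0885). That for zinc finger genes ended without chromosomes 13, 14 and X (exact test, adjusted p = 0.128) and with the TSS at the 5′ end of the gene (exact test, adjusted p = 0.0738). Corrected H3K4me3 was at 3.50% of olfactory receptors against 18.4% (exact test, adjusted p = 1.09e-17). The share of each list's covered length in the corrected H3K4me3 list was 16.3% ± 9.21 for H3K4me3 antibodies (SD, n = 8), 2.10% ± 1.76 for H3K4me2 (n = 4) and 1.18% ± 0.119 for H3K4me1 (n = 5), with H3K4me1 against H3K4me3 past the threshold (-15.1 points, exact permutation p = 0.00155, adjusted p = 0.0210). H3K4me2 against H3K4me3 (-14.2 points, exact test, adjusted p = 0.0545) and against H3K4me1 (adjusted p = 0.536) did not pass, and without EMD Millipore 05-1338 the H3K4me2 mean was 1.22%. The corrected list was made from 2 of these H3K4me3 libraries, so the measure is not independent, and a list of 20.2 Mb can only be a small share of the much longer H3K4me1 lists. The share of the corrected list found ran the other way, with 65.0% ± 20.9 for H3K4me1 (SD, n = 5), 50.1% ± 26.1 for H3K4me2 (n = 4) and 35.9% ± 24.1 for H3K4me3 (n = 8). Of its bases 95.2% lay in the Abcam ab8580 list and 26.1% in the Abcam ab12209 list.

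H3K27me3 and H3K9me3, repressive marks with 1 list each, were compared with the H3K4 lists. H3K27me3, the Polycomb mark, covered 69.7% of the ungapped genome and H3K9me3, of heterochromatin, 96.9%. Of the promoters with an H3K4 peak, 81.5% ± 4.44 also had an H3K27me3 peak for H3K4me1 (SD, n = 5), 79.0% ± 2.29 for H3K4me2 (n = 4) and 78.9% ± 3.06 for H3K4me3 (n = 8), with no pair past the threshold (exact tests, adjusted p = 0.551, 0.378 and 0.937). Of all promoters 73.9% had one, so these shares are close to the background of that list. H3K9me3 peaks lay at nearly all of them, 99.9976%, 99.9967% and 99.9879%, so that list could not separate the targets (exact tests, adjusted p = 0.857, 0.174 and 0.239). H3K27me3 peaks were at 76.9% of the promoters positive for H3K4me3 and 63.5% of the negative ones (odds ratio 1.91, Fisher's exact p = 1.09e-75, across genes). The size of this difference depends on the classes. It was 13.4 points with all lists and 7.77 points with overlap by 0.5. With fewer H3K4me3 lists the negative class, scaled to them, held only promoters in 0 lists. The difference was then 12.7 points without Abcam ab8580 and 29.1 to 31.6 points without any 1 of the others. It was 30.4 with the AR16 antibodies and 35.9 with 8-cycle libraries, which both include Abcam ab8580. The larger values thus depend on that list. The H3K27me3 list covered only 11.3% of chromosome 13 and 15.3% of chromosome 14, against a median of 70.6%. Most H3K4me3 lists were low there too. The difference was not computed without these chromosomes, so a shared lack of peaks on them was not separated from a true overlap of the marks. For H3K27me3 0 of 12 gene lists passed against other genes, with 0 at an unadjusted p under 0.05. The H3K9me3 list had a peak at 98.7% of all promoters, so that its 0 of 12 says little. Without peaks over 1 Mb, a change chosen after seeing the data, it was at 37.8% of promoters and 2 lists passed, HOX and olfactory receptor genes. All 39 HOX promoters lay under H3K9me3 peaks in the full list and 0 without those over 1 Mb, so this test reads peak length and not whether the mark is there. The widest H3K27me3 peak at a promoter, 1623295 bases on chromosome 6, took in IFNGR1, the interferon gamma receptor gene (TSS 137219385), OLIG3 (TSS 137494394), PERP (TSS 138107419), ARFGEF3, PBOV1, SMIM28, HEBP2, NHSL1, CCDC28A and ECT2L (TSS 138796087). IFNGR1, HEBP2 and CCDC28A had promoter peaks in all 17 H3K4 lists.

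Coverage differed between chromosomes in most lists. The H3K4me1 lists covered on average 9.16% of chromosome 13, 15.7% of chromosome 14 and 7.00% of chromosome X, against 39.1% of the median chromosome, and all 3 were below the median in each of the 5 lists. The H3K4me2 lists had means of 8.03%, 13.6% and 6.41%, against 27.2%, and without Cell Signaling Technologies 9725 the 3 means were 4.77%, 8.62% and 3.96%. All 3 were below the median in 3 of the 4 H3K4me2 lists and 5 of the 8 H3K4me3 lists. Chromosome 14 was at or above the median in EMD Millipore 05-1338, Abcam ab12209, Abclonal A2357 (1.32% against 1.26%) and Thermo Fisher PA5-40086 (0.775% against 0.735%). These are the 4 libraries of 12 cycles, and in all 13 H3K4 libraries of 8 cycles chromosome 14 was below the median. The H3K27me3 list covered 11.3% of chromosome 13 and 15.3% of chromosome 14 but 91.5% of chromosome X, against a median of 70.6%. The H3K9me3 list covered 97.7% of chromosome 13, 97.0% of chromosome 14 and 95.0% of chromosome X, against a median of 97.3%. Without these chromosomes the number of gene list comparisons that passed was 9.

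**Figure D5:**
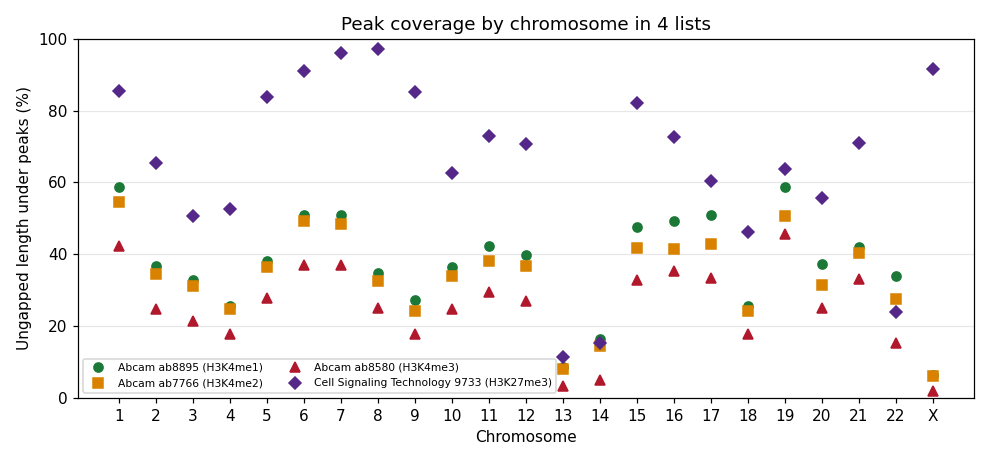
Percent of the ungapped length of each chromosome under peaks for 4 lists (Abcam ab8895 for H3K4me1, Abcam ab7766 for H3K4me2, Abcam ab8580 for H3K4me3 and Cell Signaling Technology 9733 for H3K27me3). All 3 H3K4 lists are low on chromosomes 13, 14 and X, and the H3K27me3 list on 13 and 14 but not X, where it covers 91.5%.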

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

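The tests of explanations in this part were all chosen after the results were seen. In 9 of the 27 combinations of 9 measures and 3 targets, 1 library stood far from the others of its target, and these flags fall on 4 libraries. Chance gives about 1 in 20 groups, or 1.35 here, if the measures were independent, which they are not, so this number is only a rough guide.

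Among the H3K4me3 lists, Abcam ab8580 stood apart with 721215 peaks, the next being 233923 for EMD Millipore 07-473, and with 769 Mb covered, the next being 165 Mb. A difference in amplification cycles is argued against by the other lists of 8 cycles: the largest other H3K4me3 of these, of only 3, had 14.5% as many peaks as EMD Millipore 07-473. Capture of H3K4me2 nucleosomes is 1 candidate explanation. It was tested on the parts of the Abcam ab8580 and EMD Millipore 07-473 lists that lie outside the other 6 H3K4me3 lists. These parts overlapped each of 3 other H3K4me2 lists at least 1.36 times as often as the highest of 20 shifted placements. Shifting removes any shared preference for peak-rich regions, so this overlap cannot single out H3K4me2. H3K4me1 lists were not run in this test, and Abcam ab8580 was nearest to the H3K4me1 list of Abcam ab8895 (Jaccard index 0.458). Weak true H3K4me3 in regions of H3K4me2 would give the same overlap and stays open, as does capture of H3K4me1 nucleosomes. A difference in depth, which the peak lists do not record, stays open too. No biological explanation was tested, since all libraries come from 1 cell line.

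Coverage on chromosomes 13, 14 and X was low in most H3K4 lists, with H3K4me1 means of 9.16%, 15.7% and 7.00% against 39.1% for the median chromosome. Lower copy number or local depth, which would leave only stronger peaks, was tested on the 5th percentile of the authors' value in the 14 H3K4 lists that hold one. This floor was above that of the median chromosome in 11 lists for chromosome 14, where H3K27me3 coverage was low too (15.3% against 70.6%). The H3K9me3 list, which covered 96.9% of the ungapped genome, was not low on chromosome 14 (97.0% against a median of 97.3%). A list that covers nearly the whole genome can hardly show a modest loss of depth, so it does not decide this. Lower depth remains only a candidate for chromosome 14. Chromosome 14 was however at or above the median in 3 H3K4me3 lists and 1 H3K4me2 list, so the pattern is not in every list. For chromosome 13 the floor was higher in 7 of 14 lists, and for chromosome X in 11, but the single H3K27me3 list covered 91.5% of X, so for these chromosomes lower depth and a true difference cannot be told apart. No biological explanation was tested.

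The H3K4me2 list of EMD Millipore 05-1338 had at least 300 bases of peaks within 3 kb of 10896 CpG-rich promoters. Of these promoters 333 had no peak in any of the 8 H3K4me3 lists, among them GAPDH, HPRT1, MCM5 and KDM5C. Outside chromosomes 13, 14 and X, the tenth with the most GC lacked a peak at 60 of 1032 promoters and the tenth with the least at 11 of 1024 (odds ratio 5.68, Fisher's exact p = 1.48e-09, across genes). Loss of reads or peaks at high GC is a candidate, which this test cannot separate from a true lack of H3K4me3 at such promoters. GC does not account for every case: MCM5 on chromosome 22 and KDM5C have a GC of 61.5%, below the median of 65.1% of the CpG-rich promoters with a peak. Promoters on chromosomes 13, 14 and X lacked a peak at 90 of 809, the others at 243 of 10087 (odds ratio 5.07). These chromosomes were picked for few peaks, so the ratio restates that and is no evidence of low depth, which stays open. The thresholds behind the count of 333 were set after looking at the data, and promoters that truly lack H3K4me3 stay among them. H3K4me2 lists other than EMD Millipore 05-1338 were not used for this count. No biological explanation was tested.

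EMD Millipore 05-1338 stood apart from the other H3K4me2 lists with 109654 peaks, where the next had 421187. Its promoter share of peaks was 14.9%, against 3.45% for the next, and 4.71% of its length lay in the corrected H3K4me3 list, against 1.52%. EMD Millipore 05-1338 was the only H3K4me2 library of 12 cycles, so a difference of antibody and one of cycles cannot be told apart. Active Motif 39635, with 39010 peaks of median width 25008.5 bases where the other H3K4me1 lists have 349557 to 600205 of 555 to 1005 bases, stood apart from them in promoter share of peaks, 25.0% against 4.94%, in the authors' median value, 25.2 against 10.2, and in promoters shared with H3K27me3, 89.3% against 81.0%. Wide peaks touch a promoter window more often, so its promoter share is not comparable with the others. In EpiGentek A-4031-050, 99.9881% of promoters with a peak overlapped H3K9me3, where the other 4 H3K4me1 lists had 100%. The change in TSS occupancy between promoters with and without H3K4me3 differed between H3K4me1 and H3K4me2 by -53.3 points (exact permutation p = 0.0159).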

How the results depend on the processing

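The alternatives without chromosomes 13, 14 and X, without peaks over 1 Mb and with the TSS at the 5′ end of the gene were chosen after seeing the data. Of 795 values for 34 results under 34 alternatives, 710 kept direction and side of the threshold, 26 lost a call, 13 gained one, 26 reversed and 20 counts moved by over 1.5 times. Many of the 710 kept direction by construction, since leaving out an antibody of 1 target does not move the difference between the other 2. Only the 4 comparisons of targets that passed, and the Jaccard difference, had a call to lose. For H3K4me1 minus H3K4me3 it ended in 6 of 26 runs for covered length and 10 of 28 for promoters. It ended in 5 of 27 for TSS occupancy and 5 of 25 for the share in corrected H3K4me3. These 34 results do not include the distal regions and promoter classes. Of 234 values for the distal regions, 41 lost a call, 1 gained one and 3 reversed, and of 104 for the promoter classes none did. The Jaccard difference passed under every alternative run, with permutation p from 0.00025 to 0.00734. The comparison of H3K4me1 with H3K4me2 between promoter classes, -53.3 points with all lists, ranged from -59.6 to -46.1 points with each antibody left out, and its p lies at or near the smallest possible, so the p cannot show stability. The other 2 comparisons of classes involve H3K4me3, by which the classes were made, so their passing shows nothing. Dropping peaks under 200 bases removed none, so it tests nothing. No paired analysis was possible because the labels number no antibodies across targets. Depth is unknown for every list. Fewer antibodies raise the smallest p that a test can give, which bears on the lost calls with the AR16 input, with 8 cycles and with an antibody left out; for the other changes the cause was not tested. Among the 78 named genes, the number of lists with a promoter peak moved by over 1.5 times for at most 13 genes, with overlap by 0.5. For them only the filter by value, overlap by 0.5, the 2 windows and the 3 alternatives chosen after seeing the data were run.

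For H3K4me1 minus H3K4me3, the share of promoters lost its call with peaks above the median (24.6), overlap by 0.5 (15.1), windows of 2.5 kb (24.2) and 0.5 kb (18.4), the AR16 input (17.1) and 8 cycles (22.8). With the AR16 input covered length (926.6 Mb), TSS occupancy (-62.2) and the share in corrected H3K4me3 (-12.6) lost theirs, as with 8 cycles (899 Mb, -54.1 and -12.3). Calls gained were the promoter share of peaks with overlap by 0.5 (-32.2), TSS occupancy of H3K4me2 minus H3K4me3 with the flank at 2 kb (-26.5), and the width-weighted authors' value for H3K4me1 (-11.8) and H3K4me2 (-14.1) minus H3K4me3. Gene list comparisons past the threshold, 6 as reported, were 14 with overlap by 0.5, 0 with the 2.5 kb window, 12 with 0.5 kb, 0 with the AR16 input and 0 with 8 cycles. Fisher tests of corrected H3K4me1, 2 as reported, were 1 with the 2.5 kb window and 1 without chromosomes 13, 14 and X, the call for developmental transcription factors ending in both. Those of H3K9me3, 0 as reported, were 2 without peaks over 1 Mb, HOX and olfactory receptor genes. Liver genes gained a call for corrected H3K4me2 with peaks above the median (16.7%, exact test, adjusted p = 0.0243), overlap by 0.5 (5.56%, exact test, adjusted p = 0.00115) and the 0.5 kb window (16.7%, exact test, adjusted p = 0.0242). Cell cycle genes gained one for corrected H3K4me1 with peaks above the median (95%, exact test, adjusted p = 0.0478).

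Reversals concerned differences that had not passed. H3K4me1 minus H3K4me2 became -2.38 for the promoter share of peaks and -5.52 for promoters with overlap by 0.5, -1.74 for promoters and -0.000371 for H3K9me3 overlap with the 0.5 kb window, -52964 peaks, -0.575 for promoters, -0.000417 for H3K9me3 overlap and -0.405 for the HBE1 region with 8 cycles, -0.13 for the log2 number of peaks, and -0.510 for H3K9me3 overlap without peaks over 1 Mb. H3K4me1 minus H3K4me3 became 2.11 for the authors' median value with 8 cycles and -0.374 for H3K9me3 overlap without peaks over 1 Mb. H3K4me2 minus H3K4me3 in H3K27me3 overlap became -0.457 with peaks above the median, -0.0359 with the 0.5 kb window and -0.607 with 8 cycles.

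With each antibody left out, H3K4me1 minus H3K4me2 ranged from -52964 to 121764 peaks, from 94.9 to 558.6 Mb, from -1.99 to 5.07 in promoter share of peaks, from -0.575 to 5.13 in promoters, from -36.6 to -27.2 in TSS occupancy, from -0.158 to 4.07 in median value, from -1.29 to -0.0440 in corrected H3K4me3, from 0.642 to 3.31 in H3K27me3 overlap, from -0.000417 to 0.00331 in H3K9me3 overlap, from -0.405 to 9.67 upstream of HBE1, from 0.858 to 24.5 downstream of MYC and from -20 to 8.15 upstream of GATA1. H3K4me1 minus H3K4me3 ranged from 212242 to 352540 peaks, 843 to 1061 Mb, -34.0 to -24.8 in promoter share, 20.1 to 26.0 in promoters, -62.4 to -56.5 in TSS occupancy, -17.0 to -13.7 in corrected H3K4me3 and 0.723 to 3.38 in H3K27me3 overlap. H3K4me2 minus H3K4me3 ranged from 195381 to 315931 peaks, 407 to 870.6 Mb, -36.2 to -27.0 in promoter share, 18.0 to 23.9 in promoters, -31.9 to -22.5 in TSS occupancy, -16.1 to -12.8 in corrected H3K4me3 and -0.643 to 1.15 in H3K27me3 overlap. The difference in H3K27me3 between promoters positive and negative for H3K4me3 ranged from 12.7 to 31.6 points, against 13.4 with all lists. Gene list calls ranged from 0 to 12. Every call gained came without Abcam ab8580, except that of H3K4me1 minus H3K4me3 upstream of GATA1 without Active Motif 39635. The libraries behind each lost call are named in the results above. The reversals came without Active Motif 39635, EpiGentek A-4031-050, Abcam ab7766, EMD Millipore 05-1338, Thermo Fisher 710796, Abcam ab12209, Abclonal A2357, EMD Millipore 05-745R or Thermo Fisher PA5-40086.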

Other observations

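The test in this part was chosen after the result was seen. The longest stretch outside assembly gaps with almost no peak in any K562 list lay on chromosome 9, from 25400001 to 26400000, where the 17 H3K4 lists, H3K9me3 and H3K27me3 together covered 1.65%, around TUSC1. Of the 8 longest such stretches, 6 lay on chromosome 9 between 21000001 and 31600000, one over the type I interferon genes such as IFNB1 and IFNA2 (21000001 to 21400000) and another over LINGO2 (28600001 to 29500000, 0.315% covered). H3K9me3 peaks covered 96.9% of the ungapped genome but 0.700% of the longest stretch. The stretches were picked for their low coverage, so the 1.65% restates the choice and gives no support to a loss of this DNA from the genome of these cells, which cannot be told apart from other explanations here. The whole interval was covered to 28.8%. Mappability was not tested, and the K562 inputs were not analysed here.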
